A study of Aplysia californica with 16 samples.

How the data were processed

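RNA of whole embryos, larvae and juveniles of the sea hare Aplysia californica, a marine gastropod mollusc, was measured on 16 Agilent 2-colour oligonucleotide arrays. The arrays cover 8 developmental stages, each hybridised once to each of 2 array designs, called AAA and DAA in the labels. Per the file headers, the grid of the AAA design is named an annotated array and that of the DAA design a discovery array. On every array the stage was labelled with Cy3 and a common reference, made of equal amounts of RNA from all 8 stages, with Cy5, per the labels. No dyes were swapped, so a dye effect specific to a probe drops out of differences between stages where it is the same on all arrays of a design, but not out of a single ratio. Whether it was the same on all arrays was not tested. Total RNA was linearly amplified before labelling, per the labels' protocols, which name a direct and an indirect dye method without saying which array had which, so the method could not be tested as a batch.

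The authors' scanner files give, per the file headers, the mean intensity of each spot and the median intensity of its local background in both channels, extracted with Feature Extraction 8.5.1.1. They also hold processed intensity values, background-subtracted, spatially detrended and dye-normalised by lowess, and the log10 ratio of Cy5 over Cy3 made from them, per the file headers. The deposited table of the whole series holds log10 values as well. On both designs 100% of its values equalled the scanner files' log10 ratio with the sign turned, within a tolerance of 0.005, so its values are log10 ratios of Cy3 over Cy5, rounded to 2 decimals. The medians of its columns lie between 0 and 0.02, and the match leaves no room for a further scaling or centring. That Cy3 holds the stage and Cy5 the pool is taken from the labels and is not shown by the match.

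Spot intensities were corrected with the normexp method of limma 3.58.1 in R 4.3.3, with an offset of 50, on the mean signal and median background. Each array was then normalised by loess on its own, with control spots and outlier spots at weight 0, and the log2 ratio of stage over reference was taken. Control spots and outlier spots were left out afterwards, and saturated spots were kept in the feature values. Spots of a probe were averaged, and then the probes of a feature, where a feature is the gene, contig or clone that the array files name. A feature was kept if it was well above background in Cy3 on at least 2 arrays or in Cy5 on at least 4 arrays. The counts of features at least 2-fold apart between consecutive stages left out those with a saturated Cy3 spot in either stage. The 4-fold counts of a stage left out those with a saturated Cy3 spot in that stage. The AAA arrays hold 41991 spots that are not controls, 21128 probes and 14412 features. The DAA arrays hold 42034 such spots, 41504 probes and 40974 features. Between 93.9% and 96.5% of the spots were well above background in Cy3, and between 85.8% and 95.1% in Cy5. The number of arrays limits the precision.

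Groups were taken from the labels. Because each stage has 1 array per design, the stages served as samples of 3 periods in a first comparison. These were the 3 stages before the veliger (cleavage, gastrula, trochophore), the 3 veliger stages (first veliger, hatching veliger, stage 6) and the 2 stages after metamorphosis (stage 7 and 60 h later). The periods were compared with limma on each design separately, where the error is the spread between stages of a period. A second fit took the 265 features present on both designs, each with 3 probes on each design, over all 16 arrays, with array design as a block. It compared each stage with the mean of the 7 others and with the stage before it, and tested all stages at once with an F-test. In that fit the error, on 7 residual degrees of freedom, is the spread between the 2 arrays of a stage. The labels do not say whether both arrays carried separate RNA, so these p-values measure the spread between arrays, which may be technical. Adjusted p-values are Benjamini-Hochberg values from limma, per contrast, with a threshold of 0.05.

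Tests, gene lists, alternatives and the rule for named features were fixed before the data were examined. For each period contrast and design the rule took 6 features per direction with a word name, by size among those passing or, with none passing, by smallest p. In the stage fit it took 3 features per stage with the largest excess over the other stages, and up to 6 per direction from stage 6 to stage 7. For the other steps between consecutive stages, the 4 largest changes per direction among passing features, and further members of the groups below, were chosen after their values were seen. Only 47 of the features on both designs carry a word name, and all were tested. The other features are named by contig, clone or sequence record, and no table pairing them with genes was used here. The 33 fixed gene lists were matched to the files' own names. Of these, 6 had a match and 1, transmitter synthesis and transport, had the 5 members needed for a test; ribosomal proteins, cilia, histones and all 3 lists for material other than the animal were among those with no match. The word-named features were therefore also sorted by name into 6 groups, after the names and before the values were seen, and 5 of these groups were tested with limma's camera at its preset correlation of 0.01 and with an estimated correlation.

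The scripts were tested on simulated data. With noise drawn from the spread between stages, a log2 change of 1 between veliger and pre-veliger arrays was recovered for 62% of the changed features among the 14219 of the AAA design and 51% among the 39643 of the DAA design, and a change of 3 for 96% and 92%. The changed features were drawn at random, and the median standard error over all features was 0.137 on AAA and 0.156 on DAA. These shares do not hold for features with a larger spread between stages, such as FMRFamide, with standard errors of 0.87 and 0.90. In the stage fit on 261 features the noise was instead drawn from the smaller spread between the 2 designs, under which the period fits recovered 99% of changes of 1 on both designs. There a log2 change of 0.3 from hatching veliger to stage 6 was recovered for 80% of changed features and a change of 0.5 for 100%. Alternatives were other background corrections and normalisations, the authors' processed and deposited values, Cy3 alone, other filters, the brightest probe of a feature, another variance prior, a linear trend over stages, the fit without the block, and leaving out each array. Cy3 alone means the Cy3 intensity after loess and a quantile normalisation of the mean intensity of both channels, so it still depends in part on Cy5. Scan minutes as a covariate, leaving out features with saturated spots, leaving out the trochophore and first veliger arrays, and Cy3 alone in the stage fit were added after seeing the data.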

Results

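Transcript levels were measured from cleavage to 60 h after metamorphosis in Aplysia californica, whose embryos develop in egg capsules into trochophores and then shelled, ciliated veligers, which hatch, feed in the plankton and settle to metamorphose into crawling juveniles. The 8 stages were mixed cleavage stages, gastrula, trochophore, first veliger, hatching veliger, stage 6 just before metamorphosis, stage 7 just after it, and juveniles 60 h after metamorphosis. Cleavage embryos were taken within 48 h of fertilization per the label of the AAA array, and no time was recorded for the DAA array. Each stage was set against a pool of all stages on 1 AAA array and 1 DAA array, and the labels do not say whether both carried the same RNA. Median spot intensity lay between 219 and 304 in Cy3 and between 117 and 278 in Cy5, over median backgrounds of 39 to 47. Median Cy5 intensity fell in the order in which the 16 arrays were scanned, over 135 minutes. Its correlation with scan minutes was r = -0.956 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, adjusted p = 2e-05) and rho = -0.988 (permutation p = 1e-05, adjusted p = 2e-05), and r = -0.964 without the 2 arrays farthest from the median. For Cy3 the values were r = -0.306 (permutation p = 0.254, adjusted p = 0.254), rho = -0.224 (permutation p = 0.402, adjusted p = 0.402) and r = -0.511 without those 2. These were the 2 relations computed.

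The steps between consecutive stages differed widely in size, and both designs ranked the 7 steps in the same order. From cleavage to gastrula 9.38% of the features on the AAA arrays and 9.68% on the DAA arrays differed at least 2-fold, with 760 higher and 557 lower on AAA and 2419 higher and 1398 lower on DAA. The step from hatching veliger to stage 6 came next, at 6.40% and 5.76%, with 433 higher and 469 lower on AAA and 1289 higher and 988 lower on DAA. From stage 7 to 60 h after metamorphosis 2.85% and 2.53% differed, and from gastrula to trochophore 2.85% and 2.49%. In the step from first veliger to hatching veliger the shares were 1.18% and 1.38%. Metamorphosis itself, from stage 6 to stage 7, showed 0.595% and 0.352%, and the step from trochophore to first veliger 0.163% and 0.0633%. These counts set 1 array against 1 array of a design and have no replicate check. Among the 261 features measured on both designs, the 2 designs differed by 2-fold or more in the change from trochophore to first veliger for 7 features, in that from first veliger to hatching veliger for 5, and in the other steps for 0.

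**Figure D1:**
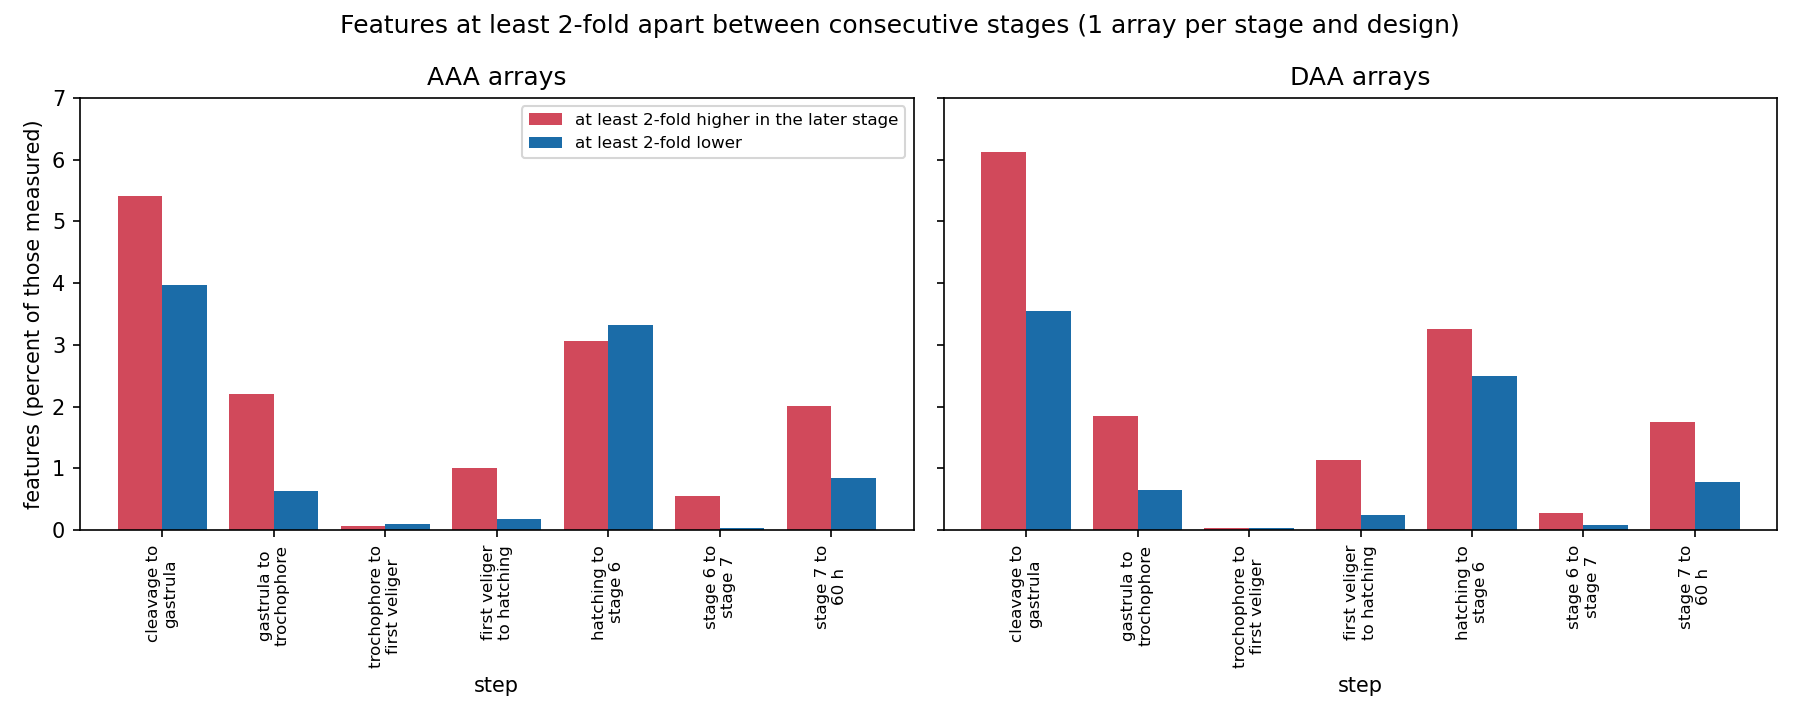
Percent of measured features (vertical axis) that were at least 2-fold higher (red bars) or lower (blue bars) in the later stage of each step (horizontal axis), for the AAA arrays on the left and the DAA arrays on the right, with 1 array per stage and design. Features with a saturated Cy3 spot in either stage were left out. The step from cleavage to gastrula, at 9.38% and 9.68% in both directions together, and that from hatching veliger to stage 6, at 6.40% and 5.76%, are the tallest on both designs.

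The correlations of log2 ratios across features fell into blocks of stages. Stage 6 and stage 7 resembled each other most, with r = 0.85 on AAA and 0.82 on DAA, followed by trochophore and first veliger, with 0.78 on both. Hatching veliger and stage 6, although both veligers, had 0.14 on both designs, and cleavage and gastrula had 0.36 and 0.32. Cleavage and hatching veliger were opposed on the AAA arrays, at -0.34, and less so on the DAA arrays, at -0.24. The direction of the ratios rests on the dyes given in the labels, and ratios of different stages to a pool of all of them can be opposed. These correlations run across features, which are not independent replicates.

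**Figure D2:**
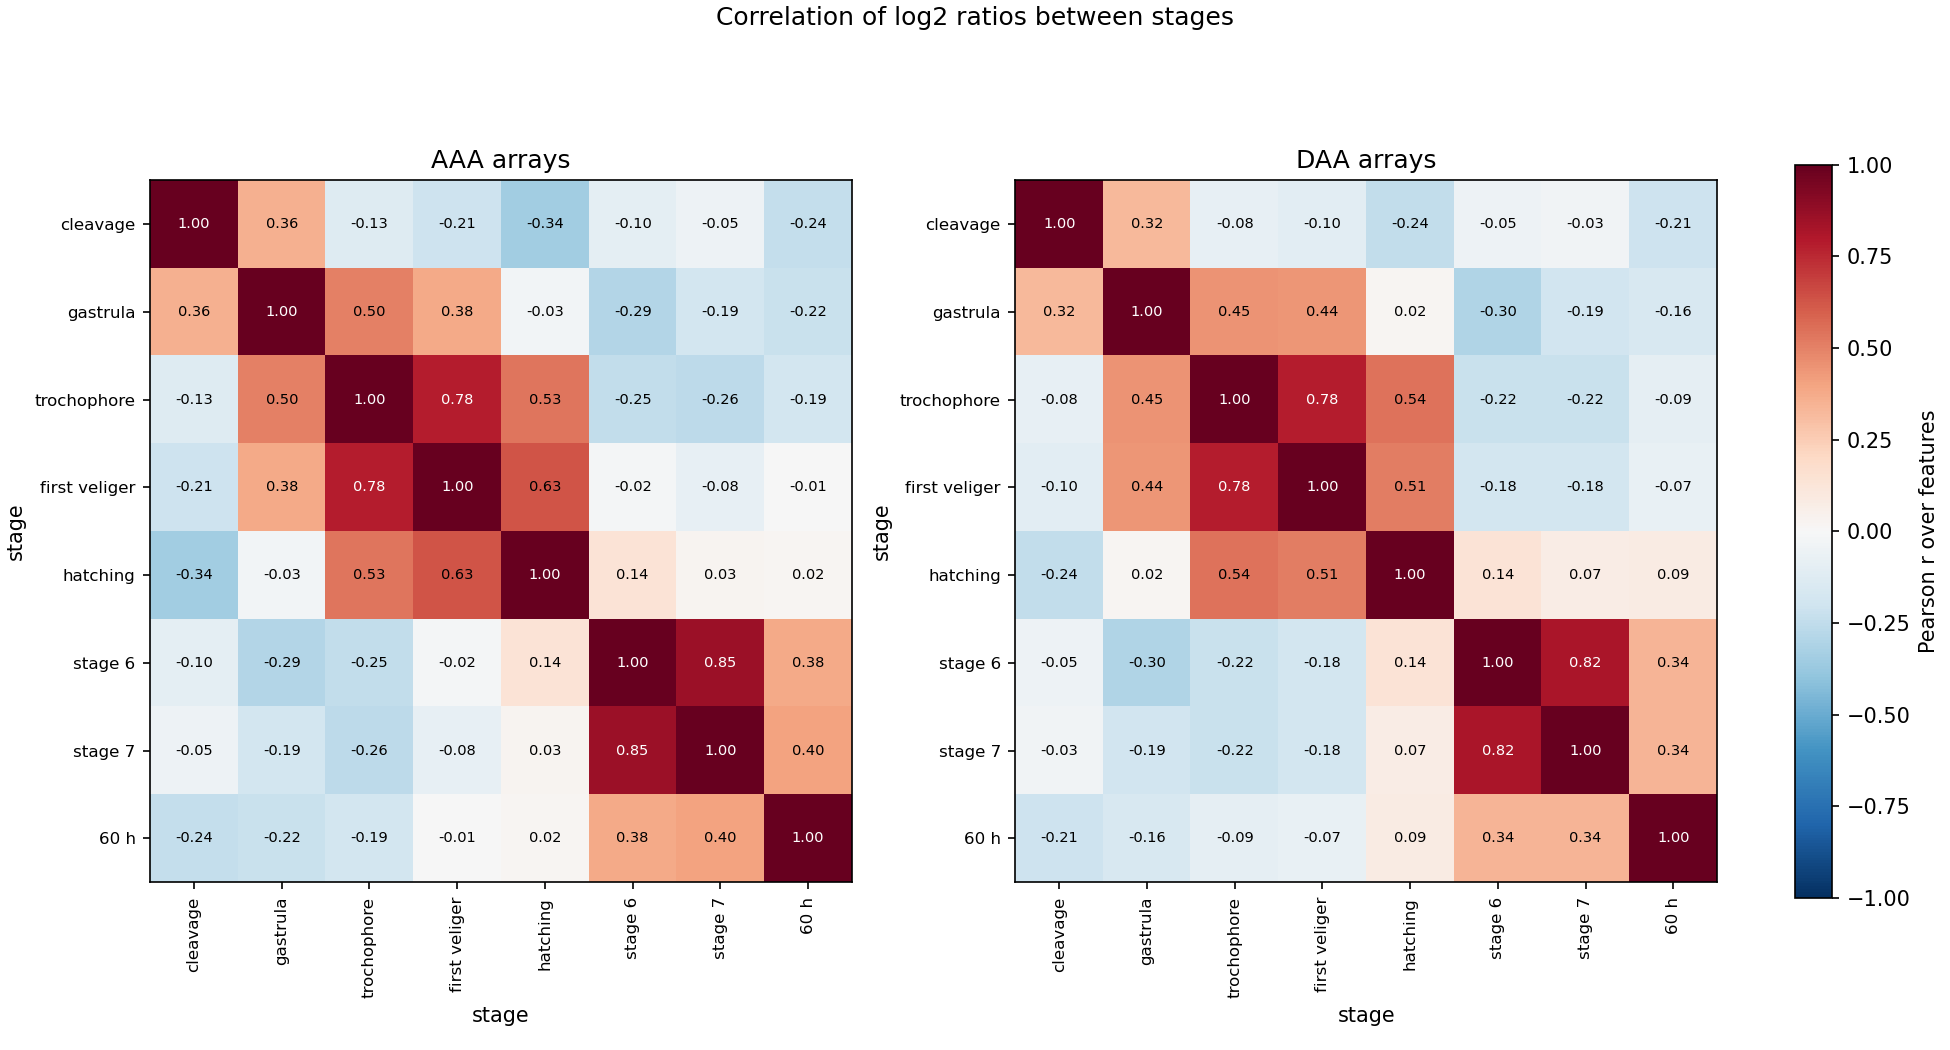
Pearson correlation of log2 ratios across features between each pair of stages (both axes), for the AAA arrays on the left and the DAA arrays on the right, with red for positive and blue for negative values. Stage 6 and stage 7 (0.85 and 0.82) and trochophore and first veliger (0.78 and 0.78) form the closest pairs of different stages.

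Cleavage embryos stood apart from the other stages in the number of features at their own level. On the AAA arrays 192 features were at least 4-fold higher in cleavage than in the mean of the other stages and 237 at least 4-fold lower, and on the DAA arrays 296 and 662. After cleavage, juveniles 60 h after metamorphosis had the most higher features, with 98 on AAA and 212 on DAA (9 and 14 lower), and gastrulae had the most lower features, with 67 and 119 (4 and 22 higher). Hatching veligers had 61 and 105 higher and 2 and 0 lower, stage 6 larvae 38 and 111 higher and 4 and 8 lower, stage 7 29 and 84 higher and 2 and 7 lower, trochophores 38 and 43 higher and 10 and 6 lower, and first veligers 23 and 26 higher and 7 and 9 lower. Higher and lower rest on the dyes given in the labels, and with the dyes exchanged they would trade places.

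In the stage fit, 219 of the 261 features tested on both designs differed between stages by limma's F-test (213 without the block), among them 39 of the 47 with a word name. Cleavage embryos were marked by Yantar transcript, at a log2 ratio of 1.71 ± 0.06 (SD, n = 2) to the pool and 2.82 ± 0.05 (SE) above the mean of the other stages (limma adjusted p = 3.4e-13). A nitric oxide synthase (NOS), which makes the gaseous messenger nitric oxide, was 0.76 higher and the glutamate receptor subunit NMDAR1-1 0.63 higher. Of the word-named features 12 were higher and 16 lower in cleavage than in the mean of the other stages, and of all features 75 and 99. All probes had the same sign in 19 of these 28 word-named calls. Over the 15 contrasts of the fit this held for 178 of 282, so the counts of word-named features and group members include calls with disagreeing probes. Low in cleavage were FMRFamide, named for a family of neuropeptides, at -3.18 ± 0.10, and Rac, a small GTPase of the actin cytoskeleton, at -0.76 ± 0.06. So were actin and beta-tubulin, at log2 ratios of -3.28 and -2.48 to the pool. At NMDAR1-1, 2 of 3 probes had the sign of the mean. The FMRFamide feature carries the same sequence record as a feature named Vanilloid, so its identity is uncertain throughout.

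From cleavage to gastrula, actin rose by 3.28 ± 0.06 (SE, log2), from -3.28 ± 0.04 (SD, n = 2) to 0.00 ± 0.02, and beta-tubulin, a subunit of microtubules, rose by 2.46 ± 0.06. Yantar fell by 1.65, Neuropeptide precursor by 1.30, the nitric oxide synthase by 0.61 and NMDAR1-1 by 0.60. Choline acetyltransferase, which makes acetylcholine, rose by 0.43, and so did a dimmer probe set of PC2, a prohormone convertase that cuts peptide precursors, by 0.68 (2 of 3 probes). Gastrulae exceeded the mean of the other stages by 0.93 in Yantar, 0.36 in choline acetyltransferase (2 of 3 probes) and 0.29 in actin. For actin that mean includes cleavage at -3.28, so the excess does not make gastrulae high in actin. At 0.00 it was below trochophores (0.63), first veligers (0.56), hatching veligers (0.28) and juveniles at 60 h (0.90). It was above stage 6 (-0.65) and stage 7 (-0.50). Over all 261 features 37 were higher and 112 lower in the gastrula than in the mean of the other stages. Of 13 features for adhesion and signalling 8 were lower (3 with median centring in place of loess). Among them were Rac at -0.77, B-amyloid precursor protein at -0.42 and Staufen, an RNA-binding protein, at -0.37. The 1 that was higher was Presenilin1-2 at 0.29 (2 of 3 probes). The call of Staufen was lost with median centring. In this step 52 features rose and 91 fell, and with median centring 43 rose and 44 fell, so the balance of directions depends on the normalisation.

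From gastrula to trochophore the FMRFamide feature rose by 3.04 ± 0.13 (SE, log2; limma adjusted p = 6.3e-09), from -3.77 ± 0.06 (SD, n = 2) to -0.73 ± 0.20, and Neuropeptide precursor rose by 1.39 ± 0.05. Of the 5 features for neuropeptides and their processing 4 rose and 0 fell (2 and 0 with median centring). Beta-tubulin rose by 0.80 and actin by 0.63. Yantar fell by 0.63, the nitric oxide synthase by 0.36 (2 of 3 probes), choline acetyltransferase by 0.24 and NMDAR1-1 by 0.22 (2 of 3 probes), the last not passing with median centring. Trochophores exceeded the mean of the other stages in beta-tubulin by 1.17 ± 0.05 and in actin by 1.01 ± 0.04. In the potassium channel Thik the excess was 0.25 ± 0.04 (2 of 3 probes). Over all features 81 rose and 18 fell in this step, against 43 and 11 with median centring. The count for trochophore against the other stages was 60 higher and 56 lower, and it came to 72 in total without the AAA trochophore array.

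Between trochophore and first veliger 10 features rose and 26 fell. The 2 designs disagreed on this step: the change correlated between them at -0.15 over the 261 features. Over the 238 with no saturated spot it correlated at 0.458. Yantar fell by 0.45 and beta-tubulin by 0.38, while Staufen rose by 0.27. With median centring 0 features passed by limma, and 29 had an unadjusted p under 0.05, so none of these 3 calls held there, and that of Staufen was also lost without the AAA trochophore or the AAA first veliger array. First veligers were still high in actin, at 0.94 above the mean of the other stages, and in beta-tubulin, at 0.73. The dimmer PC2 probe set was 0.23 higher (2 of 3 probes), a call lost with median centring and without either first veliger array.

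Hatching veligers had the highest beta-tubulin of the series, at 1.45 ± 0.07 (SD, n = 2). This was 1.95 ± 0.05 (SE) above the mean of the other stages (limma adjusted p = 3.1e-11). Neuropeptide precursor was 1.06 and FMRFamide 1.04 above the mean of the other stages. From first veliger to hatching, Neuropeptide precursor rose by 1.31 ± 0.05, FMRFamide by 1.26 ± 0.13 and beta-tubulin by 1.06 ± 0.06. Nitric oxide synthase 2 rose by 0.30 (2 of 3 probes), Yantar fell by 0.38, actin by 0.28 and choline acetyltransferase by 0.17 (2 of 3 probes). These 4 calls were lost with median centring, and that of choline acetyltransferase in 16 alternatives in all. Without the DAA hatching array those of actin and nitric oxide synthase 2 were lost too, and that of nitric oxide synthase 2 also with the authors' processed signals, the deposited values and Cy3 alone, 5 alternatives in all. In this step 53 features rose and 17 fell, against 31 and 2 with median centring. Compared with the mean of the other stages 83 features were higher and 36 lower in hatching veligers, against 69 and 15 with median centring.

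Between hatching and stage 6 beta-tubulin fell by 1.78 ± 0.06 (SE, log2) and actin by 0.93 ± 0.06, while Rac rose by 1.25 ± 0.07 and the brighter PC2 probe set by 1.19 ± 0.07 (limma adjusted p = 8.3e-08 for both). FMRFamide rose by 0.84 and Staufen by 0.54, the latter not passing with median centring, and Yantar fell by 0.61 and Neuropeptide precursor by 0.41. Of the 13 features for adhesion and signalling 7 rose and 1 fell (3 and 1 with median centring), and of the 14 receptors and channels 3 rose and 1 fell. Over all features 72 rose and 73 fell. Stage 6 larvae exceeded the mean of the other stages in FMRFamide by 2.004 ± 0.097. They did so in the brighter PC2 probe set by 1.21 ± 0.05 and in Rac by 1.15 ± 0.06. Compared with the mean of the other stages 88 of all 261 features were higher in stage 6 and 62 lower. Of the 13 adhesion and signalling features 8 were higher and 2 lower (6 and 0 with median centring). The higher ones included Staufen at 0.49, AcCYFIP at 0.36, B-amyloid precursor protein at 0.34 (2 of 3 probes) and the cell adhesion protein Fasciclin at 0.32. The call of B-amyloid precursor protein was lost with Cy3 alone, at 0.10, and that of Fasciclin without the AAA stage 6 array, at 0.22. A nicotinic acetylcholine receptor subunit was 0.40 higher, dopamine beta hydroxylase, an enzyme of transmitter amine synthesis, 0.35 higher (2 of 3 probes), and the gap junction family member Panx-1 0.28 higher. The 2 PC2 probe sets carry the same sequence record but differ in profile, and the dimmer one stood at 0.01 ± 0.06 (SD, n = 2) in stage 6.

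Across metamorphosis, from stage 6 to stage 7, 17 features rose and 25 fell. Yantar was the only word-named feature that rose, by 0.79 ± 0.06 (SE, log2; limma adjusted p = 1.6e-05). NMDAR1-1 fell by 0.42 ± 0.05 and the brighter PC2 probe set by 0.36 ± 0.07, each with 2 of 3 probes of that sign. FUR fell by 0.29 (2 of 3 probes), beta-tubulin by 0.22, Staufen by 0.21 and Neuropeptide precursor by 0.18. Of the 5 features for neuropeptides and their processing 3 fell and 0 rose, but only 1 fell with the authors' processed signals or the deposited values, and with median centring none passed. The 2 stages shared their leading features. Stage 7 exceeded the mean of the other stages in FMRFamide by 1.73, Rac by 0.94 and the brighter PC2 probe set by 0.80. With median centring 3 features passed, NMDAR1-1 being the only one of these 7 word-named calls that was kept. With the authors' processed signals 17 rose and 13 fell, and with the deposited values 17 and 12, and the calls of beta-tubulin, Staufen, FUR and Neuropeptide precursor were lost with both. Without the AAA or the DAA array of either stage, the calls of beta-tubulin, Staufen and Neuropeptide precursor were lost, that of FUR was lost without 3 of these 4 arrays, and that of the PC2 probe set without the AAA stage 7 array. Counting all alternatives, the calls of beta-tubulin, Staufen, FUR and Neuropeptide precursor were lost in 7, 13, 6 and 8. Leaving out 1 array of these stages gave 22 features without stage 6 and 23 without stage 7 on AAA, and 18 and 11 on DAA.

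From stage 7 to 60 h after metamorphosis actin rose by 1.40 ± 0.06 (SE, log2; limma adjusted p = 8.4e-09), to 0.90 ± 0.06 (SD, n = 2), and NMDAR1-1 rose by 0.67 ± 0.05. FMRFamide rose by 0.54, a call lost without the DAA stage 7 array, and choline acetyltransferase by 0.50. Beta-tubulin fell by 0.69, the brighter PC2 probe set by 0.54 and Yantar by 0.35, and these 3 calls were lost with median centring, that of the PC2 probe set also with Cy3 alone. AcCYFIP fell by 0.40, a call lost without the DAA array of either stage. Of the 13 adhesion and signalling features 5 fell and 0 rose (2 and 0 with median centring). Over all features 42 rose and 53 fell, against 32 and 13 with median centring. Juveniles exceeded the mean of the other stages in FMRFamide by 2.35 ± 0.10 and in actin by 1.32 ± 0.04. The excess of Neuropeptide precursor was 0.96 ± 0.04.

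**Figure D3:**
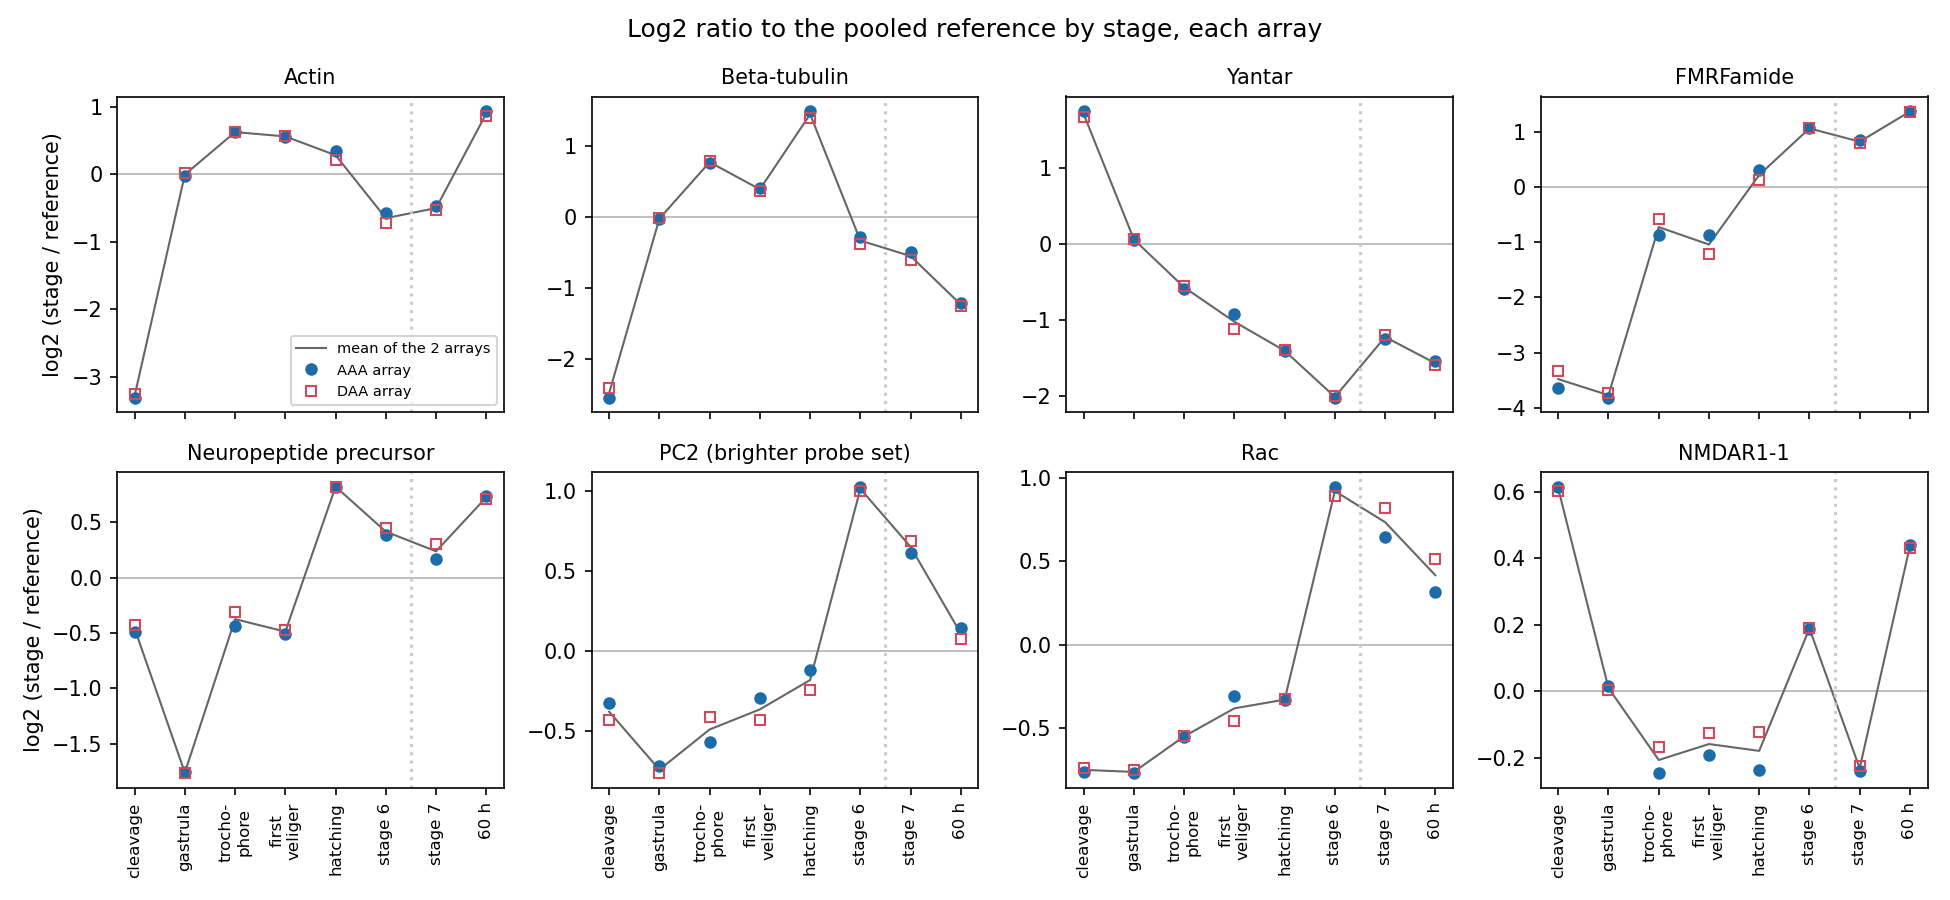
Log2 ratio of stage to pooled reference (vertical axes) over the 8 stages (horizontal axes) for 8 features, with the AAA array as filled circles, the DAA array as open squares and their mean as a line; the dotted line marks metamorphosis. Actin starts at -3.28 in cleavage, Yantar falls from 1.71, beta-tubulin peaks at 1.45 in hatching veligers, and Rac and the brighter PC2 probe set peak in stage 6.

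The groups of word-named features were also tested as sets in every contrast of the stage fit. None of the 75 camera tests passed, with a smallest adjusted p = 0.642, and a smallest adjusted p = 0.944 with an estimated correlation. The counts of members above are therefore counts of single calls, not evidence that a group stood apart from the other features.

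The comparison of periods asked which transcripts differ between embryos before the veliger, veliger larvae and animals after metamorphosis. Limma called 0 features in either contrast on either design. Veliger against pre-veliger, 1777 of 14219 features on AAA (12.5%) and 2922 of 39643 on DAA (7.37%) had an unadjusted p under 0.05, with smallest adjusted p = 0.360 and 0.658. After metamorphosis against veliger the counts were 268 (1.88%) and 724 (1.83%), with smallest adjusted p = 0.9999 and 0.99999. These unadjusted shares depend on single arrays. For veliger against pre-veliger they ran from 7.07% without gastrula to 17.1% without trochophore on AAA, and from 3.84% without hatching veliger to 13.4% without trochophore on DAA. After metamorphosis against veliger they ran from 0.591% and 0.731% without hatching veliger to 9.92% and 8.07% without stage 6. With a variance trend and robust moderation limma also called 0, with 1771 and 266 unadjusted on AAA and 2857 and 716 on DAA. The largest difference among named features that did not pass was FMRFamide, at 2.93 ± 0.87 (SE, log2) on AAA and 2.54 ± 0.90 on DAA in veligers over earlier stages. Neuropeptide precursor stood at 1.129 and 1.101, Rac at 0.80 and 0.72, and Yantar at -1.86 ± 0.61 and -1.91 ± 0.55. The other features the rule named on AAA, none passing, were Fasciclin at 0.41, the nicotinic receptor subunit at 0.29, the cadherin cad2 at 0.22, the nitric oxide synthase at -0.21, Presenilin1-2 at -0.19, choline acetyltransferase at -0.17, FUR at -0.11 and Panx-4 at -0.08. On DAA they were the brighter PC2 probe set at 0.64, Staufen at 0.27, 1 probe set of soluble guanylate cyclase at 0.16 (the other at 0.02), the nitric oxide synthase at -0.26, Vanilloid at -0.21, choline acetyltransferase at -0.19, Presenilin1-2 at -0.10 and Panx-4 at -0.07. Some of these signs turned under alternatives, on both designs those of Presenilin1-2 with the brightest probe and of the nitric oxide synthase without cleavage, and on DAA those of Staufen with the brightest probe and of Panx-4 with Cy3 alone.

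After metamorphosis against veligers, beta-tubulin stood at -1.39 ± 0.998 (SE, log2) on AAA and -1.40 ± 0.94 on DAA, FMRFamide at 0.95 and 1.08, Rac at 0.38 and 0.63, Thik at -0.23 and -0.28, Ap451 at -0.27 and -0.21, and serine dehydratase at -0.37 and -0.20. On AAA the rule also named Tolloid, a metalloprotease, at 0.18, NMDAR1-1 at 0.18, 1 probe set of Panx-3 at 0.06 (the other at -0.07), PKG at 0.05, Panx-2 at -0.12 and AMPA at -0.09. On DAA it named B-amyloid precursor protein at 0.22, Fasciclin at 0.17, the nicotinic receptor subunit at 0.16, cad3 at 0.07, FUR at -0.15 and the oxygen carrier hemocyanin at -0.12. None of these passed, and signs turned on AAA for NMDAR1-1 without the juveniles, PKG with the brightest probe, Panx-3 with Cy3 alone, AMPA with median centring and Rac with scan minutes, and on DAA for cad3 without stage 7 and hemocyanin with Cy3 alone. When single arrays were left out, limma called 58 features on AAA and 73 on DAA without stage 7, all higher in the juveniles at 60 h than in veligers. There 1 array stood for the period after metamorphosis on each design and its spread was taken from the other periods, so these calls do not show a difference between periods. Without stage 6, where every period kept at least 2 arrays, it called 52 and 5. Without the first veliger it called 0 on AAA in this contrast, and 2 for veliger against pre-veliger. On AAA it called 1 without the juveniles, where again 1 array stood for the period.

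The 5 members of the fixed list for transmitter synthesis and transport, 2 nitric oxide synthases, dopamine beta hydroxylase, histidine decarboxylase and a neurotransmitter transporter, did not move as a set in either period contrast on either design (camera adjusted p = 0.894 in all 4 tests, adjusted p = 0.928 with an estimated correlation). The list's median was 0.09 and 0.03 on AAA in the 2 contrasts, while camera's direction was up and then down. On DAA the medians were 0.00 in both contrasts. Of its members 0 passed over all features and 0 passed when adjusted over the list alone, where the smallest adjusted p was 0.488 on AAA and 0.557 on DAA.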

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

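Of the named values of the stage fit, 86 in number, 2085 were recomputed under alternatives; 2004 stayed on the same side of the threshold with the same direction, 81 no longer passed and 0 changed direction. Median centring in place of loess ended 20 of these calls, the most of any setting. The count of 219 features passing the F-test ranged from 207 to 224 when single arrays were left out, and it was 224 without the trochophore and first veliger arrays, 211 with Cy3 alone, 219 with the deposited table and 213 without the replicate block, which changed no count by over 1.5 times. Median centring gave 174. It also lowered 9 counts of single contrasts by over 1.5 times, to 95 for gastrula against the others, 62 for trochophore, 51 for the first veliger, 87 from cleavage to gastrula, 54 from gastrula to trochophore, 0 from trochophore to first veliger, 33 from first veliger to hatching, 3 from stage 6 to stage 7 and 45 from stage 7 to 60 h. The cause was not tested. Leaving out single arrays gave 72 to 128 for trochophore against the others (116 with all arrays) and 11 to 47 from stage 6 to stage 7 (42 with all arrays); a lone remaining array is there assumed to vary like the other stages.

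The 0 calls of the period comparison stayed 0 under every change of background correction, normalisation, filter, probe rule and variance prior that was run. Leaving out single arrays gave 0 to 58 on AAA and 0 to 73 on DAA. The counts with an unadjusted p under 0.05 moved by over 1.5 times: for veliger against pre-veliger to 7.07% of features on AAA (12.5% with all arrays) and to 1525 and 5309 on DAA, and for the later contrast to 84 and 1411 on AAA and to 290 and 3201 on DAA. Median centring gave 2795 on AAA in the first contrast and scaling between arrays 1105 on DAA in the second. A linear trend over the 8 stages called 611 features on AAA (423 rising, 188 falling) and 809 on DAA (629 and 180). With scan minutes as a covariate, chosen after seeing the data, the periods gave 3 on AAA and 0 on DAA, and the trend 1 and 0. Of 902 recomputed values of named features in the period comparison, none of which passed, 889 kept their direction. The 13 that changed sign include 4 that did so when single arrays were left out, where the nitric oxide synthase ranged from -0.42 to 0.052 on AAA and from -0.49 to 0.013 on DAA (positive without cleavage), NMDAR1-1 from -0.16 to 0.52 on AAA (negative without 60 h) and cad3 from -0.015 to 0.16 on DAA (negative without stage 7). With the brightest probe Presenilin1-2 came to 0.32 and 0.43, PKG to -0.10 and Staufen to -0.054. With Cy3 alone the Panx-3 probe set at 0.065 came to -0.012, Panx-4 to 0.087 and hemocyanin to 0.018, with median centring AMPA to 0.0092 and with scan minutes Rac to -0.041. The cause was not tested. Scan date and slide could not be run as blocks, because each slide holds 1 array and all were scanned on the same day. Signal over background limits Cy5 more than Cy3, since Cy5 fell over the scanning period.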

Other observations

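The tests of other splits of the stages, of exchanged arrays and of saturated spots, and the fits with scan minutes, were chosen only after the result was seen.

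Ordered along development, the trend fit gave the FMRFamide feature a slope of 0.78 ± 0.11 (SE, log2 per stage; limma adjusted p = 0.0232) on AAA and 0.73 ± 0.11 (adjusted p = 0.0274) on DAA. Its course was uneven, with 3.04 between gastrula and trochophore, while its mean went from -3.48 in cleavage to -3.77 in the gastrula, from -0.73 in trochophores to -1.04 in first veligers and from 1.06 in stage 6 to 0.82 in stage 7. The slope of Rac was 0.25 ± 0.05 per stage on DAA (adjusted p = 0.0477) and stood at 0.23 ± 0.05 on AAA (adjusted p = 0.0546, not passing). Yantar stood at -0.41 ± 0.10 per stage on AAA (adjusted p = 0.0562) and -0.40 ± 0.09 on DAA (adjusted p = 0.0651), neither passing. Of the features on both designs the trend called 22 on AAA and 13 on DAA, 12 of them the same. With scan minutes in the same fit 1 feature passed on AAA and 0 on DAA. The share with an unadjusted p under 0.05 went from 25.9% to 18.5% on AAA and from 22.83% to 16.99% on DAA. All 611 and 809 features called without scan minutes kept their sign. They had been picked for a strong slope over stage order, which correlated with scan minutes at 0.486 on AAA and 0.444 on DAA. Their sign could therefore hardly turn, and its keeping does not speak against a drift. With scan minutes the slope of FMRFamide was 0.75 ± 0.13 on AAA (limma adjusted p = 0.09996) and 0.65 ± 0.11 on DAA (adjusted p = 0.110). That of Rac was 0.25 ± 0.06 and 0.27 ± 0.06. Stage order and scan order are partly tied in these arrays, and a second term also leaves fewer degrees of freedom, so the loss of calls alone does not show that a drift made the trend.

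The arrays of trochophore and first veliger correlated less between the designs than those of other stages. Across the 261 features the 2 designs correlated at 0.86 for trochophore and 0.75 for first veliger, against 0.96 to 0.99 for the other stages, although the median absolute difference between designs, 0.07 for both, was no larger than the 0.08 of hatching veligers. The change from trochophore to first veliger correlated at -0.15 between designs. On AAA the trochophore array was scanned at 16 minutes and the first veliger array at 128 minutes, and on DAA at 135 and 8 minutes, so the loss of Cy5 with scan time runs the opposite way on the 2 designs. Over the 238 features with no saturated spot, an exchange of the 2 arrays on a design is argued against. There the change correlated at 0.458 (bootstrap 95% interval 0.275 to 0.603), with 140 features of the same sign. Each stage then correlated at 0.95 with itself between designs, against 0.89 and 0.86 for the crossed pairs. The test was first set over all 261 features, where -0.15 is what an exchange would give and the crossed pairs, at 0.88 and 0.84, exceeded the same-stage ones, and was restricted to unsaturated features after that value was seen. Other values go with an exchange. It would pair scan times of 16 with 8 and 128 with 135 minutes, near each other as in the other stages. Hatching veliger correlated at 0.541 with trochophore and 0.512 with first veliger on DAA, against 0.535 and 0.626 on AAA. An exchange therefore stays open. Saturation is a candidate explanation: the median disagreement was 0.61 log2 units over the 23 features with a saturated spot and 0.11 over the rest, 5.45 times as much. Saturated Cy5 spots numbered 387 on the trochophore and 107 on the first veliger array of AAA, and 81 and 254 on DAA. On both designs the array scanned later had fewer, so saturation and loss of Cy5 were not separated here. Loss of Cy5 was examined with Cy3 alone, where the change correlated at 0.332 (0.147 to 0.510). Those values were normalised with both channels and still depend on Cy5, so whether its loss contributes stays open. No biological explanation was tested.

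The contrast of veliger and pre-veliger arrays called 0 features on both designs, and among the 10 splits of these 6 arrays into 3 and 3 the highest count of any other split was 7 on each. With 0 features in the real split, all 10 splits count as at least as large whatever the data, so this comparison cannot show whether chance made the grouping, and 10 splits would be too few for a share under 0.05 in any case.

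A hypothesis that the ratios run as labelled, with the stage in Cy3 and an equal pool in Cy5, was tested on features whose log2 ratio spanned at least 3 units. If so, the mean linear ratio over the 8 stages should lie near 1. Its median was 1.02 over 419 features on AAA and 1.03 over 916 on DAA. The median of the inverted ratio was 1.97 and 1.91, just under the bound of 2 set in advance, so the stricter part of the test was missed. Ratios above 8-fold, which an equal pool of 8 stages does not allow, occurred in 0.477% and 0.218% of these features. Ratios below an 8th, which exchanged dyes would not allow, occurred in 23.9% and 20.1%. For these features the inverted medians and the ratios below an 8th argue against exchanged dyes, while the test as set in advance stayed undecided.

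Many contigs carry probes for both strands. A hypothesis that both strands are transcribed and regulated separately was tested where both were bright. The median correlation across the 8 stages between the strands was 0.36 over 426 contigs on AAA and 0.20 over 2078 on DAA. For random pairs it was 0.01 and 0.01, so the excess was 0.355 on AAA and 0.188 on DAA. This argues against separate regulation as a rule for all these contigs, not against transcription of both strands. Correlations were under 0 for 27.0% and 38.5% of the contigs, against 49.5% and 49.7% of random pairs. The excess therefore does not say for how many contigs the hypothesis fails, and for the others the question is open.

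A hypothesis that transcripts of amidated peptide precursors rise between hatching veliger and stage 6 was tested on probes that encode 2 or more glycines followed by 2 basic residues. Their median change was 0.24 over 6 features on AAA, at the 96.9th percentile of 10000 random sets of like brightness, and 0.49 over 12 features on DAA, at the 99.99th. Both lie above the 95th percentile set in advance. A control motif with alanine in place of glycine lay at the 46.9th percentile on AAA, with 2 features, and at the 96.1st on DAA, with 5 features and a median of 0.29, so the excess on DAA may not be specific to amidation sites. These percentiles describe 1 array per stage and design.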
